A study of Homo sapiens with 16 samples.

How the data were processed

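RNA was measured by short-read sequencing in 16 samples of BeWo cells, 2 in each of 8 groups. The groups crossed genotype (control cells or cells with TFEB knocked out by CRISPR-Cas9, called KO), treatment (dimethyl sulfoxide, DMSO, or 50 µM forskolin, FSK) and time (12 or 24 h). Per the labels' protocols, total RNA was taken up in TRIzol, mRNA was selected by its poly(A) tail, and libraries were made with a PCR-free MGIEasy kit. The submitters' processing notes name the genome build hg38, STAR 2.7.9a, Subread, featureCounts 2.0.1 and DESeq2, without saying what each was used for. Per the labels, the deposited table held raw read counts per gene, as whole numbers with no normalisation by the authors. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of a gene and of a gene overlapping it on the other strand cannot be told apart. Reads of near-identical copies, such as the CGB, PSG and CSH or GH2 genes, are likewise uncertain between the copies.

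The table had 60583 genes and 16 sample columns, each matched to a sample by its name, and no per-sample column was left unused (0 columns). No entry was something other than a gene (0 entries), and 3 symbols had the form of a date and were kept as written. Total counts ran from 26925327 to 32152335 per library. A count of 0 over a group was given a floor of 3 counts, and counting intervals were exact conditional intervals of a ratio of 2 Poisson counts at the 95% level. These floors and intervals cover counting error only.

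Everything after the counts was computed here in R 4.3.3. The test was the quasi-likelihood F-test of edgeR 4.0.16 on the counts as deposited, with TMM scaling, the default expression filter by group and a robust fit. It used 1 mean for each of the 8 groups, so that all 16 libraries shared the estimate of spread with 8 residual degrees of freedom. The filter kept 18939 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, 2-sided. Fold changes are on the log2 scale, with a standard error (SE) derived from the test, and levels are TMM-normalised CPM (counts scaled to library size), as mean ± SD over the 2 libraries of a group. The 15 contrasts were FSK against DMSO in each genotype and time (4), KO against control in each treatment and time (4), the difference of the FSK response between KO and control at each time (2), 24 h against 12 h in DMSO in each genotype (2), the change of the FSK response from 12 to 24 h in each genotype (2), and the difference between genotypes of that change (1).

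Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01 between genes, adjusted over the 21 lists in a contrast. The lists were placental peptide hormones, pregnancy-specific glycoproteins, other syncytiotrophoblast markers, cell fusion genes, steroidogenesis, cytotrophoblast markers, extravillous trophoblast markers, lysosomal hydrolases and membrane proteins, V-ATPase subunits, autophagy, MiT/TFE and Rag GTPase feedback genes, cell cycle, cAMP/CREB response, cholesterol biosynthesis, integrated stress response, p53 targets, interferon-stimulated genes, hypoxia and glycolysis, markers of other cell types, mitochondrially encoded mRNAs and replication-dependent histones. They held 488 symbols, of which 463 matched the table, and some genes were on more than 1 list. Camera asks whether a list stood apart from the other genes. Beside it stand the adjusted p of camera with a correlation estimated from the data and, as an alternative, fry, which asks whether the members moved one way on balance.

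The carry-over test took the genes called with FSK in control cells at one time and gave their median difference of the FSK response between KO and control at the other time, which rests on other libraries. It was set against 10000 random gene sets of the same size and similar expression (2000 sets in the alternatives). Gene coordinates were taken from the RefSeq table of GRCh38 by Entrez identifier and are 1-based.

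The genes named in the text follow a rule. They are 11 fixed genes (TFEB, TFE3, MITF, GCM1, ERVW-1, ERVFRD-1, CGA, CGB3, CGB5, CGB8 and SDC1); the 5 largest changes in each direction among called genes with an average log2 CPM of at least 1 and, outside the interactions, no overlap between the libraries compared; and, for each list described, up to 4 members with the lowest adjusted p and any called member that went against the list's majority. Of the largest changes, and of the members of a list that camera did not call, the text names only some. Groups, contrasts, lists, tests, this rule and the alternatives were fixed before the data were examined.

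Scripts were tested on data simulated from the real genes, library sizes and 1 mean per gene. For FSK against DMSO in control cells at 12 h, with 18939 genes, edgeR called 97 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2, with 19 false calls. For the FSK response difference at 24 h it called 92 and 100 of 100, with 6 false calls. The real KO FSK pair lay further apart. Camera and fry called 0 of 20 unchanged sets of uncorrelated genes, and the raised set was called. The alternatives were RLE scaling, library size alone, no filter on low counts, a filter of 1 CPM in 2 libraries, a fit with the replicate number as a block, DESeq2 1.42.0, a fit of only the groups compared, leaving out each library in turn, the other list tests, and picking genes at 2-fold or more for the carry-over test.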

Results

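Transcript levels were measured by poly(A) RNA sequencing in BeWo cells, a human choriocarcinoma line that is used as a model of villous cytotrophoblasts because it fuses into syncytia when cAMP rises. The cells were control cells or cells with TFEB knocked out (KO). TFEB is a transcription factor of the MiT/TFE family that drives lysosomal and autophagy genes. Each kind of cell received the solvent DMSO or 50 µM forskolin (FSK), an activator of adenylyl cyclase, for 12 or 24 h, which made 8 groups with n = 2 libraries each. The libraries held 26925327 to 32152335 counts and 16173 to 17345 genes with at least 10 counts. Mitochondrially encoded transcripts took 5.52 to 8.1% of the counts, and the 10 most abundant genes of a library took 6.79 to 8.7%.

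The labels call the replicates biological but do not give the number of clones behind the KO cells. Each KO comparison therefore sets the cells sequenced under one label against those under the other. The p-values of edgeR measure the spread between libraries. Across the 16 libraries the first principal component held 36.9% of the variance, the second 31.8% and the third 12.1%. No pair of replicates held the same values. The chi-square of a pair's counts per degree of freedom was 2.06 to 6.32 in 7 groups. The pair of KO cells in FSK at 24 h lay further apart at 18.3.

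TFEB mRNA was lower in all 8 KO libraries than in any of the 8 control libraries. In control cells TFEB (chromosome 6, 41683978 to 41736223 in hg38) stood at 85.6 ± 2 CPM in DMSO and 124 ± 4.5 in FSK at 12 h (SD, n = 2), and at 98.9 ± 1.71 and 111 ± 3.01 at 24 h. In KO cells it stood at 56.3 ± 0.88 and 46.6 ± 0.195 CPM at 12 h and at 48.1 ± 7.01 and 34.2 ± 2.67 at 24 h. The log2 fold change of KO against control was -0.60 ± 0.07 (SE) in DMSO at 12 h, -1.04 ± 0.07 in DMSO at 24 h, -1.41 ± 0.07 in FSK at 12 h and -1.69 ± 0.07 in FSK at 24 h, with adjusted p from 2e-15 to 2.39e-07 (edgeR quasi-likelihood test). The position of the edit is not given, and counts over the whole gene do not show whether the remaining transcripts carried it. The counts separate the 2 labels but do not show the loss of the protein. MITF, a relative of TFEB, fell in all 4 comparisons, by log2 fold changes from -2.82 to -2.34. TFE3, another relative, fell in FSK, to -0.19 at 12 h and -0.41 at 24 h. In DMSO it stood at -0.14 at 12 h (adjusted p = 0.0957, and 0.019 in a fit of only the groups compared) and 0.02 at 24 h (adjusted p = 0.877). The TFE3 call at 12 h had an adjusted p of 0.0361 and was lost with DESeq2 (adjusted p = 0.0558) and without control FSK replicate 2 (log2 fold change -0.11), KO FSK replicate 1 (-0.16) or KO FSK replicate 2 (-0.21).

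**Figure D1:**
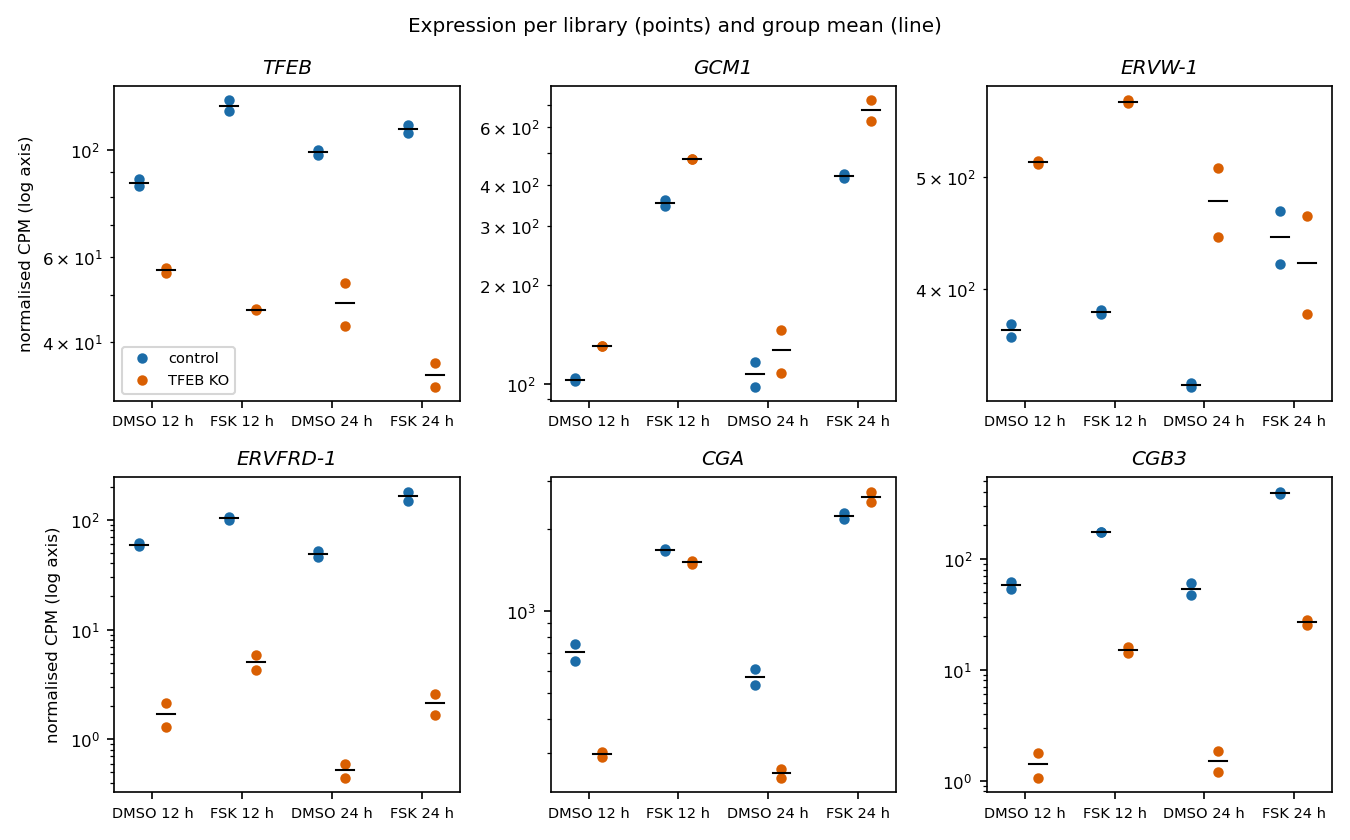
Normalised CPM on a log axis for TFEB, GCM1, ERVW-1, ERVFRD-1, CGA and CGB3 in each library (points, n = 2 per group) and as group means (lines), with control cells in blue and KO cells in orange, in DMSO and FSK at 12 and 24 h. TFEB, ERVFRD-1 and CGB3 lie lower in KO than in control cells in each treatment and time, and CGB3 and CGA rise with FSK in both.

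The first question was what FSK changed in control cells, in which raised cAMP is the stimulus for fusion. Hormone genes rose. CGA, the alpha subunit of chorionic gonadotropin, went from 705 ± 69.3 to 1671 ± 11 CPM at 12 h (SD, n = 2; log2 fold change 1.25 ± 0.07, adjusted p = 3.19e-12) and from 572 ± 54.4 to 2227 ± 76.8 at 24 h (1.96 ± 0.07, adjusted p = 1.47e-15). CGB3, CGB5 and CGB8, near-identical genes of the beta subunit whose reads are uncertain between copies, rose by log2 fold changes of 1.61 to 1.63 at 12 h and 2.86 to 3.01 at 24 h. GCM1, a transcription factor of syncytiotrophoblast differentiation, rose by 1.78 ± 0.12 and 1.99 ± 0.12. ERVFRD-1, which encodes the fusogen syncytin-2, rose by 0.81 ± 0.12 and 1.76 ± 0.12, and SDC1, a syncytial surface proteoglycan, by 0.63 ± 0.06 and 1.25 ± 0.06. ERVW-1, which encodes syncytin-1, rose at 24 h (0.42 ± 0.08, adjusted p = 0.000148), and its value at 12 h was 0.05 ± 0.08 (adjusted p = 0.643). TFEB itself rose at 12 h (0.53 ± 0.07) and stood at 0.16 ± 0.07 at 24 h (adjusted p = 0.0581). RLE scaling (0.17, adjusted p = 0.0484), no filter on low counts (0.18, 0.0193) and a fit of only the groups compared (0.16, 0.00305) called TFEB at 24 h. TFE3 fell at 12 h (-0.62 ± 0.06) and stood at -0.14 ± 0.06 at 24 h (adjusted p = 0.0832), where library size alone (-0.30, adjusted p = 0.000522), a filter of 1 CPM in 2 libraries (-0.16, 0.0292) and only the groups compared (-0.14, 0.0331) called it. MITF stood at 0.01 ± 0.17 and 0.06 ± 0.16 (adjusted p = 0.968 and 0.808).

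Among the 21 gene lists, the cAMP/CREB response stood above the other genes with the lowest camera p. Of its 18 members 15 rose at 12 h and 16 at 24 h, and 0 fell (camera, adjusted p = 7e-09 and 7.14e-10). Members that rose at 12 h included the phosphodiesterase PDE4D (2.07), the nuclear receptor NR4A3 (3.37), FOSB (2.08) and the kinase SIK1 (2.98). Adjusted over the list alone, 15 rose and 1 fell at 12 h. Here and below, the count adjusted over the list alone was the same as that over all genes tested where it is not given. Of 17 placental peptide hormones 13 rose at 12 h and 13 at 24 h (camera, adjusted p = 1.66e-06 and 2.41e-07, and adjusted p = 0.0619 and 0.0455 with an estimated correlation). They included PGF, an angiogenic growth factor (2.49 and 2.67), and ADM, adrenomedullin (1.23 and 2.03). CSH1, placental lactogen, fell (-1.55 and -1.06). Other syncytiotrophoblast markers rose in 14 and 15 of 20 members, or 16 and 15 adjusted over the list alone (camera, adjusted p = 0.000194 and 4.31e-06), with HSD11B2, which inactivates cortisol, at 1.33 and 2.66. The efflux pump ABCG2 fell (-0.39 and -0.23). Steroidogenesis genes rose in 10 of 13 at both times (camera, adjusted p = 0.000464 and 0.000109), led by CYP11A1, which makes pregnenolone (2.02 and 2.39), and its electron donor FDX1 (1.29 and 1.37). SRD5A1 fell (-0.31 and -0.54), as FDXR did at 24 h (-0.22).

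Extravillous trophoblast markers rose in 9 of 17 at 12 h and 12 at 24 h (camera, adjusted p = 0.00317 and 9.36e-07), among them the adhesion molecule MCAM (3.01 and 2.82) and LAIR2 (1.90 and 2.32). ITGA5 (-0.45) and PLAC8 (-1.53) fell at 12 h. Cytotrophoblast markers fell in 13 and rose in 5 of 24 at 12 h (camera, adjusted p = 0.0155, and adjusted p = 0.094 with an estimated correlation). The list was not called at 24 h (12 fell and 8 rose, adjusted p = 0.0971, but 0.038 with no filter on low counts). The basal-cell factor TP63 (-2.10 and -2.06), EPCAM (-0.91 and -1.52) and TEAD4 (-1.21 and -1.72) fell at both times. ELF5 (1.78 and 0.99), TFAP2A (0.79 and 1.09), GATA3 (0.51 and 0.73), MSX2 (0.51 and 0.60) and TFAP2C (0.28 and 0.79) rose. Cell fusion genes were not called at 12 h (9 rose and 5 fell of 19, camera, adjusted p = 0.36). They stood higher at 24 h (10 rose and 3 fell, or 10 rose and 4 fell adjusted over the list alone; adjusted p = 0.0236, and adjusted p = 0.168 with an estimated correlation). That call was lost with a filter of 1 CPM in 2 libraries (adjusted p = 0.0551). The endogenous retroviral envelope gene ERVV-1 rose (1.31 and 2.43), as did DYSF, a membrane repair gene (1.13 and 1.42). SLC1A5 (-1.17 and -1.06) and SLC1A4 (-1.19 and -0.99), amino acid transporters, and TJP1 (-0.39 and -0.50) fell. MYOF (-0.50) and ANO6 (-0.45) fell at 12 h.

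V-ATPase subunits, which acidify lysosomes, rose in 11 of 20 at 12 h and 10 at 24 h (camera, adjusted p = 0.0121 and 0.00873, and adjusted p = 0.101 and 0.0924 with an estimated correlation), or 11 at both times adjusted over the list alone. Adjusted over the list alone 3 fell at 12 h. ATP6V1C2 rose by 0.83 and 0.65, and ATP6V1B1 fell (-0.69 and -0.83), as did ATP6V1E1 at 12 h (-0.20) and ATP6V0E2 at 24 h (-0.47). With library size alone the 24 h call was lost (adjusted p = 0.114). Interferon-stimulated genes fell in 7 and 9 of 15, or 8 and 10 adjusted over the list alone (camera, adjusted p = 0.0112 and 0.00873, and adjusted p = 0.357 and 0.297 with an estimated correlation), among them STAT1 (-0.84 and -0.91) and IFI6 (-0.76 and -1.52). ISG15 (0.80 and 1.04), STAT2 (0.31 and 0.56) and BST2 (0.38 and 0.44) rose. Genes of the integrated stress response fell in 12 and rose in 3 of 21 at 12 h, or 3 rose and 14 fell adjusted over the list alone (camera, adjusted p = 0.0019, and adjusted p = 0.245 with an estimated correlation). VLDLR (-1.82) and the cystine transporter SLC7A11 (-1.52) fell, and SLC3A2 (0.55), SLC7A5 (0.51) and CEBPB (0.69) rose. The list was not called at 24 h (9 rose and 5 fell, or 9 rose and 6 fell adjusted over the list alone; adjusted p = 0.507). At 24 h 16 of 23 cholesterol biosynthesis genes fell (camera, adjusted p = 0.000109, and adjusted p = 0.0566 with an estimated correlation), among them FDFT1, squalene synthase (-1.72), and DHCR24 (-1.78). INSIG1 (0.68), PMVK (0.23) and NSDHL (0.19) rose. Hypoxia and glycolysis genes rose in 15 of 19 at 24 h (camera, adjusted p = 4.07e-05, and adjusted p = 0.101 with an estimated correlation), among them the glucose transporter SLC2A1 (1.36) and BNIP3 (0.85), with P4HA1 lower (-0.65). Camera called neither of these lists at 12 h (adjusted p = 0.548 and 0.644).

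The lysosomal hydrolase and membrane protein list was not called. Of its 50 members 8 rose and 13 fell at 12 h and 9 rose and 16 fell at 24 h, or 9 rose and 18 fell adjusted over the list alone (camera, adjusted p = 0.181 and 0.321). GLB1, beta-galactosidase, fell (-0.77 and -1.26), and CD63 rose (0.31 and 0.57). With library size alone, which moves the median of all genes down with FSK, camera called the list lower (adjusted p = 0.0329 and 0.0364). Autophagy genes rose in 16 and fell in 5 of 36 at 24 h (camera, adjusted p = 0.0522, but 0.0481 with RLE scaling, 0.0115 with no filter, 0.0414 without control DMSO replicate 2 and 0.0402 without control FSK replicate 1), with WIPI1 higher at both times (1.01 and 0.98), and the receptor SQSTM1 higher at 24 h (0.79). Camera did not call MiT/TFE and Rag GTPase feedback genes (adjusted p = 0.181 and 0.868, median 0.05 and mean -0.13 at 24 h), pregnancy-specific glycoproteins (0.168, but 0.0294 with no filter, and 0.308), cell cycle genes (0.644 and 0.507), p53 targets (0.593 and 0.868, median 0.01 and mean -0.13 at 12 h), mitochondrially encoded mRNAs (0.997 and 0.297, but 0.0191 at 24 h without control FSK replicate 1) or replication-dependent histones (0.557 and 0.868). Markers of other cell types moved both ways, with the endothelial CDH5 (1.81 and 2.39) and the fibroblast COL1A1 (1.69 and 1.88) higher and PDGFRA lower (-2.87 and -3.53). The list was not called (adjusted p = 0.24 and 0.239, but 0.0426 at 24 h with library size alone).

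Over all genes tested, FSK called 3624 genes higher and 3365 lower at 12 h, and 4234 higher and 3990 lower at 24 h (edgeR), of which 1588 and 2228 changed at least 2-fold. The genes called at both times were 2772 higher and 2452 lower, where independent lists would share 810.2 and 708.9. WNT3A, a Wnt ligand, rose from 2 to 112 ± 6.93 CPM at 12 h (5.81 ± 0.11) and by 6.36 ± 0.11 at 24 h. The transcription factor OVOL2 fell most at both times (-4.97 and -4.85), followed by S100A14 at 12 h (-3.93) and ENC1 at 24 h (-4.25). Scaling by library size alone moved the median of all genes by -0.085 at 12 h and -0.164 at 24 h in control cells, and by -0.105 and -0.149 in KO cells. The share of calls that were higher then went from 51.9 to 36.7% and from 51.5 to 28.8% in control cells, and from 52.4 to 33.9% and from 49.5 to 29.5% in KO cells.

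**Figure D2:**
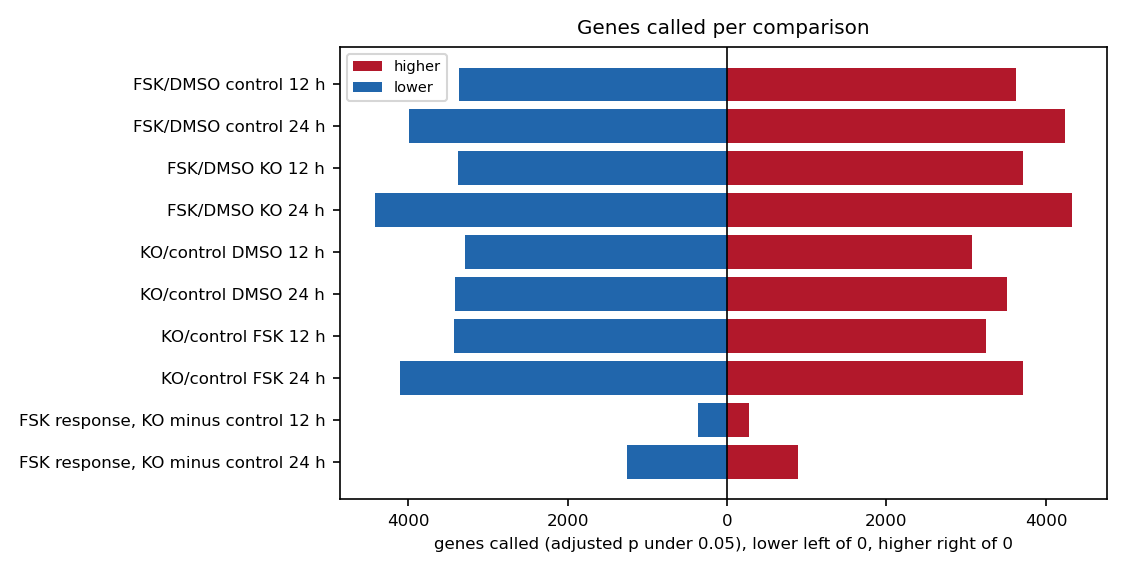
Number of genes called higher (bars to the right) and lower (bars to the left) at an adjusted p under 0.05 by edgeR in 10 comparisons of BeWo cells. FSK and genotype each call more genes than the difference of the FSK response between genotypes does.

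The same comparison within KO cells asked which part of the FSK response was present without intact TFEB. GCM1 rose from 130 ± 0.19 to 480 ± 0.431 CPM at 12 h (SD, n = 2; 1.88 ± 0.12, adjusted p = 2.28e-07) and from 127 ± 26.5 to 675 ± 67.1 at 24 h (2.41 ± 0.12, adjusted p = 1.98e-08). CGA rose by 2.34 ± 0.07 and 3.37 ± 0.07, to 2618 CPM at 24 h. The CGB genes rose steeply from a low level, CGB5 by 3.93 ± 0.13 and 4.48 ± 0.12, CGB3 by 3.42 ± 0.23 and 4.15 ± 0.21, and CGB8 by 3.70 ± 0.17 and 4.80 ± 0.16. ERVFRD-1 rose from 1.71 ± 0.584 to 5.03 ± 1.11 CPM at 12 h (1.54 ± 0.27, adjusted p = 0.00044) and from 0.522 ± 0.11 to 2.12 ± 0.629 at 24 h (2.03 ± 0.41, adjusted p = 0.00116). The 24 h call was lost without KO FSK replicate 2 (log2 fold change 1.68, adjusted p = 0.0644). SDC1 rose (0.70 ± 0.06 and 1.04 ± 0.06), TFEB (-0.27 ± 0.07 and -0.49 ± 0.08) and TFE3 (-0.67 ± 0.07 and -0.57 ± 0.06) fell, and ERVW-1 did not pass (0.17 ± 0.07 and -0.18 ± 0.07, adjusted p = 0.079 and 0.0647). ERVW-1 was called at 24 h without KO DMSO replicate 1 (-0.27, adjusted p = 0.00967) or KO FSK replicate 2 (-0.32, 3.26e-05), with library size alone (-0.32, 0.000552) and with no filter (-0.14, 0.0363), and at 12 h with no filter (0.15, 0.0201) and only the groups compared (0.17, 0.00447). MITF did not pass either (-0.36 ± 0.34 and 0.15 ± 0.28, adjusted p = 0.454 and 0.689).

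Lists were then tested in KO cells. The cAMP/CREB response rose in 14 and 16 of 18 (camera, adjusted p = 1.9e-07 and 2.4e-09), with 1 lower adjusted over the list alone at each time. Placental peptide hormones rose in 11 and 13 of 17 (adjusted p = 1.79e-06 and 3.8e-08, and adjusted p = 0.0562 and 0.0433 with an estimated correlation), with PGF at 2.25 and 2.37. CSH1 fell (-1.04 and -0.55), as did CSH2 at 12 h (-0.51). Other syncytiotrophoblast markers rose in 13 and 16 of 20 and fell in 0 (adjusted p = 3.81e-05 and 2.96e-06), among them OVOL1 (2.28 and 2.96) and TENT5A (1.18 and 1.88). Steroidogenesis genes rose in 10 and 9 of 13 (adjusted p = 0.000217 and 0.00178, and adjusted p = 0.0496 and 0.053 with an estimated correlation), with CYP11A1 at 1.87 and 2.25. SRD5A1 (-0.32) and FDXR (-0.19) fell at 24 h. Extravillous trophoblast markers rose in 9 and 12 of 17, or 10 and 12 adjusted over the list alone (adjusted p = 0.0141 and 2.71e-06, and adjusted p = 0.0562 and 0.00422 with an estimated correlation). PLAC8 fell (-2.43 and -0.56), as did ITGA1 (-0.91), ASCL2 (-0.63) and ITGA5 (-0.20) at 12 h. Cytotrophoblast markers fell in 13 and 14 of 24 (adjusted p = 0.00215 and 0.00258, and adjusted p = 0.0514 and 0.0468 with an estimated correlation), or 14 and 15 adjusted over the list alone, with TP63 at -1.96 and -2.90. GATA3 (0.64 and 0.94), TFAP2A (0.87 and 0.91), KRT18 (0.28 and 0.51) and KRT8 (0.14 and 0.41) rose, as did EGFR at 24 h (1.00).

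Cell fusion genes were not called in KO cells (7 rose and 5 fell at 12 h and 8 rose and 5 fell at 24 h of 19, or 8 and 5 and 9 and 8 adjusted over the list alone; camera, adjusted p = 0.411 and 0.309), nor were cholesterol biosynthesis genes (5 rose and 8 fell at each time of 23; 0.804 and 0.193). In KO cells the integrated stress response fell in 16 of 21 at 12 h, or 18 adjusted over the list alone (camera, adjusted p = 6.54e-07, and adjusted p = 0.0562 with an estimated correlation), with SLC7A11 at -2.84 and the pseudokinase TRIB3 at -1.74, and SLC3A2 (0.62), CEBPB (0.68) and SLC7A5 (0.38) higher. It was not called at 24 h (0.0665), but camera called it with no filter (0.0113) and without KO DMSO replicate 2 (0.0217) or KO FSK replicate 1 (0.0343). Interferon-stimulated genes fell in 10 and 11 of 15 (adjusted p = 0.000206 and 0.000345, and adjusted p = 0.146 and 0.2 with an estimated correlation), with IFI6 at -1.12 and -1.93. STAT2 rose (0.33 and 0.31), as did BST2 at 24 h (0.30). Hypoxia and glycolysis genes rose in 15 of 19 at 24 h (adjusted p = 4.77e-05, and adjusted p = 0.119 with an estimated correlation), with P4HA1 (-1.08) and PDK1 (-0.36) lower. They were not called at 12 h (0.51, median 0.13 and mean -0.13). V-ATPase subunits rose in 8 of 20 at 12 h, or 11 adjusted over the list alone (adjusted p = 0.00686, and adjusted p = 0.0692 with an estimated correlation), with ATP6V1B1 (-1.15) and ATP6V0E2 (-0.30) lower. They were not called at 24 h (0.216, median 0.09 and mean -0.02). MiT/TFE and Rag GTPase feedback genes fell in 3 of 10 at 12 h (adjusted p = 0.0171, and adjusted p = 0.146 with an estimated correlation), namely TFE3, RRAGD (-1.80) and FNIP2 (-0.88). That list call was lost without KO DMSO 12 h replicate 1 (adjusted p = 0.0735). Camera did not call the lysosomal list in KO cells (0.295 and 0.166) nor autophagy genes (0.694 and 0.418), pregnancy-specific glycoproteins (0.295 and 0.145), markers of other cell types (0.238 and 0.183), cell cycle genes (0.337 and 0.623), p53 targets (0.922 and 0.995), mitochondrially encoded mRNAs (0.475 and 0.623) or histones (0.51 and 0.433), nor MiT/TFE genes at 24 h (0.216). Library size alone called the lysosomal list lower at 24 h (adjusted p = 0.0184) and called the glycoproteins and the markers of other cell types there (0.0406 each). No filter called the glycoproteins at both times (0.0204 and 0.0256) and those markers at 12 h (0.0341).

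FSK called 3712 genes higher and 3368 lower in KO cells at 12 h, and 4328 higher and 4420 lower at 24 h (edgeR). Of these, 2699 higher and 2443 lower at 12 h were called in the same direction in control cells, which share no library with them, where independent lists would share 710.3 and 598.4. At 24 h the shared genes were 3032 and 2829, against 967.6 and 931.2. The correlation of fold changes across genes between control and KO cells, over genes that are not independent replicates, was 0.705 at 12 h and 0.719 at 24 h. The metallothionein MT1A (7.16 and 4.76) and AQP2 (6.42 and 6.24) were among the largest rises. GPC4, a glypican, went from 0 counts over the group in DMSO to 6 in FSK at 24 h. It was 2.3-fold higher at a floor of 3 counts over the group, with the counting error of the 6 not covered. The call of GPC4 was lost without KO DMSO replicate 1, KO DMSO replicate 2 or KO FSK replicate 1. NRP2 (-3.97 and -6.03) and OVOL2 (-6.11 and -5.35) were among the largest falls, with S100A14 (-4.14) at 12 h and ENC1 (-5.18) at 24 h.

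KO and control cells were then compared within each treatment and time, to ask what differed with the TFEB genotype. The beta subunit genes of chorionic gonadotropin and ERVFRD-1 stood far lower in KO cells. CGB5 differed by -5.56 ± 0.12 in DMSO at 12 h (adjusted p = 3.05e-17), -5.22 ± 0.12 in DMSO at 24 h, -3.26 ± 0.09 in FSK at 12 h and -3.75 ± 0.08 in FSK at 24 h (adjusted p = 2.05e-17), and CGB3 by -5.35, -5.16, -3.54 and -3.87. CGB8 differed by -5.26, -5.36, -3.20 and -3.55. Summed over the CGB genes and LHB, which share reads, control cells held 250 ± 25.4 and 235 ± 33.2 CPM in DMSO at 12 and 24 h and KO cells 7.01 ± 0.503 and 7.31 ± 0.742 (SD, n = 2). In FSK control cells held 774 ± 12.5 and 1850 ± 123 and KO cells 79.7 ± 2.57 and 142 ± 10.2. ERVFRD-1 stood at 59 ± 2.55 and 164 ± 22 CPM in control cells in DMSO at 12 h and FSK at 24 h, and its log2 fold change in KO cells ran from -6.52 ± 0.23 in DMSO at 24 h to -4.38 ± 0.16 in FSK at 12 h.

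Of the other fixed genes, GCM1 rose in KO cells in FSK (0.44 ± 0.12 at 12 h and 0.67 ± 0.12 at 24 h, adjusted p = 0.013 and 0.000776) and stood at 0.34 ± 0.12 and 0.24 ± 0.12 in DMSO (adjusted p = 0.0575 and 0.16). In DMSO it was called at 12 h with no filter (0.33, adjusted p = 0.0187), with 1 CPM in 2 libraries (0.33, 0.0398) and with only the groups compared (0.33, 4.62e-08), and at 24 h without KO DMSO replicate 2 (0.44, 0.000377). The FSK call at 12 h was lost without control FSK replicate 1 (adjusted p = 0.0522), control FSK replicate 2 (0.0848), KO FSK replicate 1 (0.0562) or KO FSK replicate 2 (0.0593). ERVW-1 rose in DMSO (0.48 ± 0.08 and 0.53 ± 0.08) and in FSK at 12 h (0.61 ± 0.08), and stood at -0.07 ± 0.08 in FSK at 24 h (adjusted p = 0.478), where it was called without KO FSK replicate 2 (-0.22, adjusted p = 0.00356). CGA was lower in DMSO (-1.24 ± 0.07 and -1.17 ± 0.07), did not pass in FSK at 12 h (-0.15 ± 0.07, adjusted p = 0.0921, but 0.00227 with no filter and 0.0015 with only the groups compared) and was slightly higher in FSK at 24 h (0.23 ± 0.07, adjusted p = 0.00743). That last call was lost without control FSK replicate 1 (0.20, adjusted p = 0.0761) or KO FSK replicate 2 (0.17, adjusted p = 0.0687). SDC1 fell in DMSO at 12 h (-0.28) and in FSK (-0.22 and -0.35), with -0.13 in DMSO at 24 h (adjusted p = 0.0786, but 0.0375 with RLE scaling, 0.0314 with no filter and 0.0163 with only the groups compared).

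Other syncytiotrophoblast markers fell in 11, 12, 10 and 12 of 20 in DMSO at 12 and 24 h and FSK at 12 and 24 h, or 14, 14, 11 and 13 adjusted over the list alone (camera, adjusted p = 8.83e-05, 2.17e-05, 0.000529 and 0.00444, and adjusted p = 0.0536 and 0.0511 in FSK with an estimated correlation). HSD11B2 (-4.76 in DMSO at 12 h and -4.93 in FSK at 24 h), the aromatase gene CYP19A1 (-3.91 and -4.47) and the galectin gene LGALS16 (-4.06 and -3.30) fell. ABCG2 rose in each comparison (0.20 to 0.88) and ALPP, placental alkaline phosphatase, rose in FSK (0.46 and 0.75). EBI3 (0.55) and ZNF554 (0.33) rose in DMSO at 12 h and TENT5A (0.78) in FSK at 24 h. Steroidogenesis genes fell in 6, 6, 8 and 10 of 13, or 8, 9, 8 and 10 adjusted over the list alone (camera, adjusted p = 0.00368, 0.00103, 0.000862 and 0.000616, and adjusted p = 0.076, 0.0539, 0.0677 and 0.0511 with an estimated correlation), with the sulfatase STS at -1.68 and -1.70. SRD5A1 rose (0.42 to 0.72), as did CYP11A1 in DMSO at 12 h (0.26).

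Hormone genes went both ways, and the list of placental peptide hormones was not called in any of the 4 comparisons (5 rose and 8 fell, 7 rose and 7 fell, 6 rose and 7 fell and 7 rose and 7 fell of 17; adjusted p = 0.138, 0.348, 0.355 and 0.609). Adjusted over the list alone the members that fell numbered 8, 8, 9 and 8, and those that rose 5, 7, 6 and 8. Against the CGB genes, the placental lactogen genes CSH1 (2.82 in DMSO at 24 h and 3.33 in FSK at 24 h) and CSH2 (2.92 and 3.15) and the growth hormone variant GH2 (1.72 and 2.38) rose. These copies share reads. Pregnancy-specific glycoproteins rose in 2, 2, 2 and 3 of 5, with 1 lower in FSK at 12 h adjusted over the list alone. The list was not called (adjusted p = 0.217, 0.221, 0.452 and 0.124). In FSK at 24 h camera called it with no filter (0.0099) and without control FSK replicate 2 (0.0165) or KO FSK replicate 1 (0.0429). PSG3 stood at 1.78 to 2.11. Cell fusion genes were called lower in FSK at 24 h (4 rose and 10 fell of 19, camera, adjusted p = 0.0386, and adjusted p = 0.224 with an estimated correlation). The call was lost with a filter of 1 CPM in 2 libraries (adjusted p = 0.082) and without control FSK replicate 2 (0.0879) or KO FSK replicate 2 (0.0995). ERVV-1 (-2.30) and ERVV-2 (-3.36) fell, and the lipid transporter MFSD2A (2.29), CAPN6 (1.35), LGALS1 (0.30) and GCM1 rose. Camera did not call this list in the other comparisons (adjusted p = 0.272, 0.386 and 0.159).

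Cytotrophoblast markers fell in 10, 12 and 15 of 24 in DMSO at 24 h and FSK at 12 and 24 h, or 11, 13 and 15 adjusted over the list alone (camera, adjusted p = 0.0152, 0.0105 and 0.000616, and adjusted p = 0.0987, 0.088 and 0.0511 with an estimated correlation), with MSX2 at -0.79, -1.22 and -1.51 and EPCAM at -0.62, -1.14 and -1.30. TP63 (1.60, 1.40 and 0.75) and VGLL1 (0.41, 0.38 and 0.27) rose, as did KRT7 in DMSO at 24 h (0.17), KRT18 (0.38), KRT8 (0.31), KRT7 (0.28) and GATA3 (0.16) in FSK at 12 h, and EGFR in FSK at 24 h (0.58). DMSO at 12 h was not called (0.0998), but camera called it with no filter (0.00896) and without control DMSO replicate 2 (0.0439) or KO DMSO replicate 2 (0.0413). Extravillous trophoblast markers stood higher in DMSO (10 rose and 5 fell at 12 h and 8 rose and 3 fell at 24 h of 17, or 11 and 5 at 12 h and 9 and 5 at 24 h adjusted over the list alone; camera, adjusted p = 0.0157 and 0.0376, and adjusted p = 0.076 and 0.112 with an estimated correlation). LAIR2 (1.97 and 2.01) and ITGA5 (0.82 and 0.80) rose, and ITGA1 (-2.28 and -3.94), ASCL2 (-0.85 and -0.59) and ADAM19 (-0.42 and -0.19) fell. At 12 h TIMP3 fell (-1.32), and FN1, fibronectin, was at least 5.76-fold lower. The 24 h call was lost with a filter of 1 CPM in 2 libraries (adjusted p = 0.0545) and without control DMSO replicate 1 (0.0508) or KO DMSO replicate 2 (0.0665). In FSK the list was not called (0.25 and 0.301, median 0.10 and mean -0.09 at 24 h).

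Among lists close to TFEB's known role, MiT/TFE and Rag GTPase feedback genes fell in 3, 3, 4 and 5 of 10 and rose in 0 (camera, adjusted p = 0.0479, 0.0285, 0.00974 and 0.00427, and adjusted p = 0.273, 0.206, 0.126 and 0.101 with an estimated correlation), or 6 in FSK at 24 h adjusted over the list alone. The folliculin partner FNIP2 (-2.24 to -2.61), MITF and the Rag GTPase RRAGC (-0.64 to -1.12) fell. The call in DMSO at 12 h was lost with library size alone (adjusted p = 0.0528) and without control DMSO replicate 1 (0.1). Lysosomal hydrolases and membrane proteins went both ways and the list was not called (13 rose and 13 fell, 15 rose and 9 fell, 9 rose and 10 fell and 13 rose and 10 fell of 50; adjusted p = 0.845, 0.348, 0.944 and 0.743; medians 0.01, 0.08, 0.03 and 0.03, means -0.06, 0.03, -0.05 and -0.03). Adjusted over the list alone, 14, 17, 10 and 15 rose and 13, 10, 11 and 11 fell. PPT1, palmitoyl-protein thioesterase (-0.77 in DMSO at 12 h and -0.76 in FSK at 24 h), PSAP, prosaposin (-0.49 and -0.57), and NPC1 (-0.65 and -0.29) fell in each comparison. Autophagy genes were not called (adjusted p = 0.791, 0.257, 0.793 and 0.765), although the receptor SQSTM1 fell (-0.80 in DMSO at 12 h and -1.58 in FSK at 24 h) and the kinase ULK1 rose (0.66 and 0.49). V-ATPase subunits fell in 12 of 20 in FSK at 24 h (camera, adjusted p = 0.012, and adjusted p = 0.101 with an estimated correlation), with ATP6V0B at -0.58 and ATP6V1A higher (0.15). They were not called elsewhere (0.217, 0.219 and 0.25).

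Of 17 p53 targets, 13, 11, 10 and 11 fell (camera, adjusted p = 6.53e-05, 0.00293, 0.00169 and 0.00564, and adjusted p = 0.0541 and 0.0511 in FSK with an estimated correlation), among them MDM2 (-0.40 to -0.82) and FDXR (-0.55 to -0.68). TP53INP1 rose in DMSO at 24 h (0.59) and in FSK (0.51 and 0.80). CDKN1A (0.17) and GDF15 (0.18) rose in DMSO at 24 h and BTG2 (0.23) in FSK at 24 h. Cholesterol biosynthesis genes fell in 15, 16 and 14 of 23 in DMSO at 12 and 24 h and FSK at 12 h, or 15, 18 and 16 adjusted over the list alone (camera, adjusted p = 0.000131, 1.99e-05 and 0.00215, and adjusted p = 0.076, 0.0486 and 0.108 with an estimated correlation). Lanosterol synthase, LSS, fell (-1.14, -1.45 and -1.19), and LDLR (0.38, 0.26 and 0.50) and HMGCS1 (0.15, 0.42 and 0.33) rose. The list was not called in FSK at 24 h (0.209). Hypoxia and glycolysis genes fell in 10, 12, 10 and 12 of 19, or 12, 13, 12 and 12 adjusted over the list alone (camera, adjusted p = 0.0104, 0.00045, 0.0167 and 0.00564, and adjusted p = 0.295, 0.167, 0.352 and 0.28 with an estimated correlation), with SLC2A1 at -1.34 in DMSO at 24 h and -1.08 in FSK at 24 h. BNIP3L rose in each (0.18 to 0.47), ADM in the first 3 (0.49, 0.73 and 0.24) and HK1 in DMSO at 12 h (0.36).

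Interferon-stimulated genes rose in DMSO, in 5 and 6 of 15, or 7 and 6 adjusted over the list alone (camera, adjusted p = 0.00461 and 0.00309, and adjusted p = 0.295 and 0.28 with an estimated correlation), with IFI6 at 1.31 at 24 h and BST2, tetherin, at 1.38 and 1.40. They were not called in FSK (0.201 and 0.819). The integrated stress response fell in FSK, in 15 and 18 of 21, or 15 and 19 adjusted over the list alone (camera, adjusted p = 2.22e-05 and 1.96e-06, and adjusted p = 0.102 and 0.0836 with an estimated correlation), among them CHAC1 (-2.20 and -2.20), PHGDH at 12 h (-1.34) and ATF4 at 24 h (-0.54). It was not called in DMSO (0.927 and 0.304). Replication-dependent histones, whose mRNAs lack a poly(A) tail and stood at a median of 1.38 CPM, fell in 7 of 9 in DMSO at 12 h and 9 in FSK at 12 h (camera, adjusted p = 0.00368 and 0.000425, and adjusted p = 0.156 and 0.088 with an estimated correlation), or 8 and 9 adjusted over the list alone, with H2BC12 at -0.70 and -1.02. At 24 h 3 fell in DMSO and 3 in FSK, or 3 and 5 adjusted over the list alone. Neither time was called (0.221 and 0.101), but camera called FSK with no filter (0.0124) and without control FSK replicate 1 (0.0263). Camera called no other list in these comparisons, with adjusted p of 0.217, 0.98, 0.944 and 0.301 for cell cycle genes, 0.845, 0.786, 0.859 and 0.412 for the cAMP/CREB response (median 0.01 and mean -0.01 in FSK at 12 h), 0.543, 0.43, 0.201 and 0.506 for mitochondrially encoded mRNAs, and 0.988, 0.431, 0.859 and 0.743 for markers of other cell types (medians 0.24, 0.10 and 0.54 against means -0.58, -0.50 and -0.51 in the last 3).

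**Figure D3:**
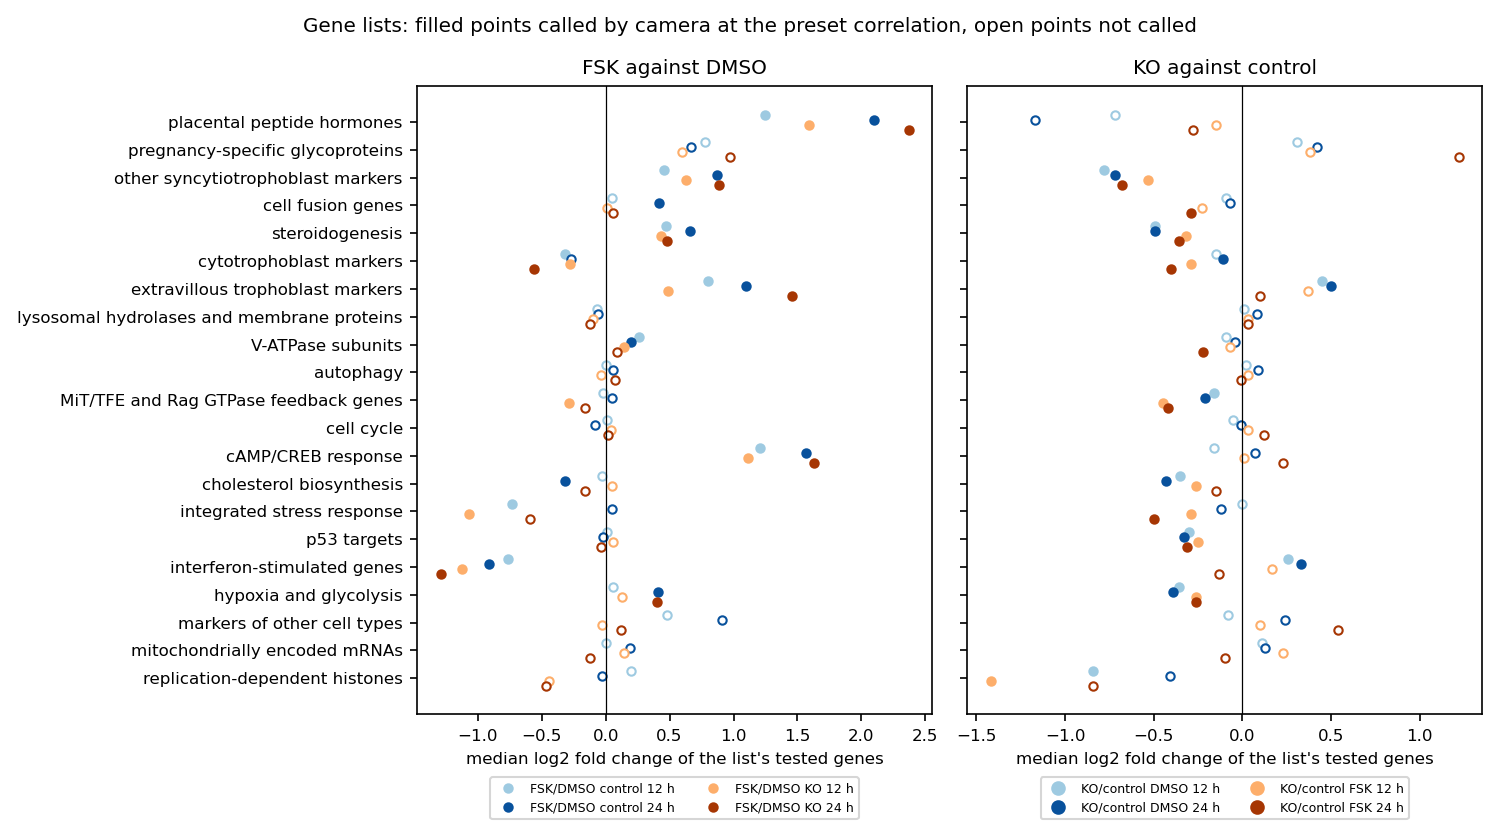
Median log2 fold change of each gene list for FSK against DMSO (left) and KO against control (right) at 12 and 24 h, with filled points where camera called the list at its preset correlation. The cAMP/CREB response and the peptide hormones stand higher with FSK, and other syncytiotrophoblast markers stand lower in KO cells.

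KO against control called 3071 genes higher and 3287 lower in DMSO at 12 h, 3514 and 3412 in DMSO at 24 h, 3242 and 3421 in FSK at 12 h, and 3717 and 4105 in FSK at 24 h (edgeR), with 1511, 1560, 1664 and 2090 changed at least 2-fold. Between 12 and 24 h in DMSO, which share no library, 2172 higher and 2410 lower calls were shared, against 569.8 and 592.2 for independent lists. A few genes well expressed in control cells were nearly absent from KO libraries, so that their fitted fold changes depend on the prior count. LRP2, the endocytic receptor megalin (chromosome 2, 169127109 to 169362534), was lower in DMSO at 12 h by a ratio of 3040 (95% counting interval 545 to 120000), CCKBR, the gastrin receptor, by 1410 (390 to 11600), and ATIC, an enzyme of purine synthesis, by 1230 (421 to 5980). GPC4 was lower by 1400 (252 to 55500) and NSD1, a histone methyltransferase, by 538 (184 to 2610). In DMSO at 24 h GPC4 was at least 402-fold lower, and ANKRD13C was lower by a ratio of 583 (199 to 2830). In FSK at 12 h CCKBR was at least 894-fold lower. In FSK at 24 h PRKAA2, a catalytic subunit of AMPK, was lower by a ratio of 380 (67.8 to 15000), in a region where its neighbours were lower too (median -1.64). Among the largest rises was IL2RB, an interleukin-2 receptor chain (3.03 to 3.53).

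Whether FSK acted differently in KO than in control cells was tested as the difference of the 2 responses. CGA and the CGB genes responded more strongly in KO cells in terms of fold change. The list of placental peptide hormones was not called (4 rose and 1 fell at 12 h, or 5 rose and 2 fell adjusted over the list alone, and 6 rose and 4 fell at 24 h, of 17; camera, adjusted p = 0.113 and 0.127). CGB5 had a difference of 2.31 ± 0.16 at 12 h (adjusted p = 4.89e-08) and 1.47 ± 0.16 at 24 h (adjusted p = 2.76e-06), CGB8 of 2.06 ± 0.20 and 1.81 ± 0.21, CGB3 of 1.80 ± 0.28 and 1.29 ± 0.27, and CGA of 1.10 ± 0.10 and 1.41 ± 0.10. In FSK the CGB genes nonetheless stayed below control levels. The CGB3 difference at 24 h was lost without KO DMSO replicate 1 (1.01, adjusted p = 0.075) or KO FSK replicate 2 (1.20, adjusted p = 0.0577). ERVFRD-1 (0.72 ± 0.30 and 0.27 ± 0.45, adjusted p = 0.295 and 0.798) and GCM1 (0.10 ± 0.17 and 0.43 ± 0.17, adjusted p = 0.893 and 0.152) did not pass. GCM1 at 24 h was called without KO DMSO replicate 1 (0.66, adjusted p = 0.000372) and with no filter (0.45, 0.0457), and ERVFRD-1 at 12 h with no filter (0.70, 0.00259) and only the groups compared (0.72, 0.0292). ERVW-1 responded less in KO cells at 24 h (-0.60 ± 0.11, adjusted p = 0.000833). TFEB differed too (-0.80 ± 0.10 and -0.65 ± 0.10), as did TFE3 at 24 h (-0.43 ± 0.09). The differences of TFE3 at 12 h (-0.05, adjusted p = 0.915), MITF (-0.37 and 0.10, adjusted p = 0.784 and 0.907) and SDC1 (0.06 and -0.22, adjusted p = 0.833 and 0.0823) did not pass, although SDC1 at 24 h did without KO FSK replicate 1 (-0.30, adjusted p = 0.00189).

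Several genes that FSK raised in control cells stayed near their DMSO level in KO cells. HTRA4, a placental serine protease, went from 23 to 285 ± 2.16 CPM in control cells at 24 h and from 12.5 to 11.3 ± 1.07 in KO cells (difference -2.58 ± 0.11 at 12 h and -3.78 ± 0.10 at 24 h, adjusted p = 4.37e-14 and 4.64e-18). SP6, a transcription factor, did likewise (-2.73 ± 0.13 at 24 h). At 12 h WNT3A responded less (-4.64), a call that was lost without KO DMSO replicate 1 (-2.96, adjusted p = 0.629). ATL3 responded more at 12 h (1.93), but not without KO DMSO replicate 2 (1.74, adjusted p = 0.0888) or KO FSK replicate 2 (1.73, adjusted p = 0.0882).

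**Figure D4:**
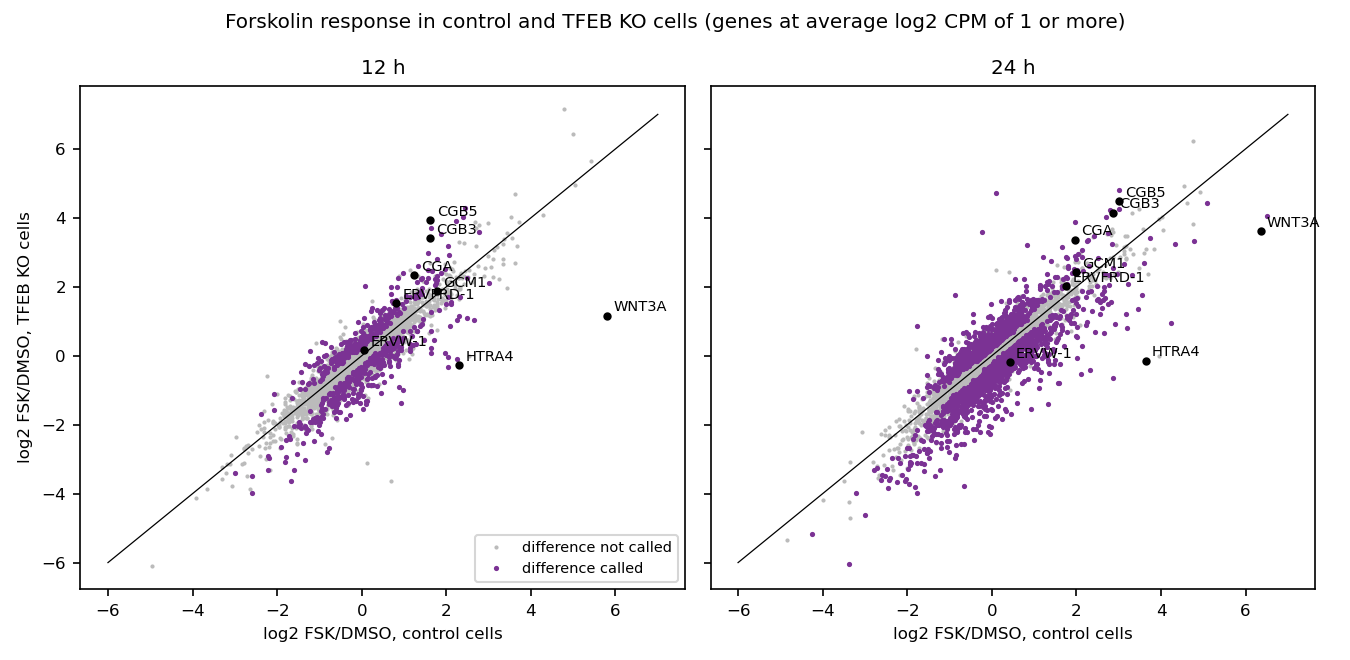
Log2 fold change of FSK against DMSO in control cells (horizontal) and in KO cells (vertical) at 12 and 24 h, 1 point per gene with an average log2 CPM of at least 1, in purple where the difference between genotypes was called. CGB5, CGB3 and CGA lie above the diagonal, and WNT3A and HTRA4 lie below it.

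The list of integrated stress response genes responded more negatively in KO cells at both times. Differences were called lower for 8 of 21 members at 12 h and 11 at 24 h, or 13 at each time adjusted over the list alone (camera, adjusted p = 6.86e-11 and 1.59e-07, and adjusted p = 0.113 and 0.097 with an estimated correlation), with PHGDH, of serine synthesis (-1.15), and TRIB3 (-0.80) at 12 h, CHAC1 (-1.95) and DDIT3 (-1.16) at 24 h, and SLC7A11 at both (-1.32 and -1.92). Interferon-stimulated genes followed, with 3 and 6 of 15 members lower, or 3 and 9 adjusted over the list alone (camera, adjusted p = 0.0416 and 0.000169, and adjusted p = 0.615 and 0.244 with an estimated correlation), such as ISG15 (-0.82 and -0.81). The 12 h call of that list was lost with library size alone (adjusted p = 0.0565), a filter of 1 CPM in 2 libraries (0.0507), and without control DMSO replicate 1 (0.066), control FSK replicate 1 (0.145), KO DMSO replicate 1 (0.367) or KO FSK replicate 1 (0.158). At 24 h cholesterol biosynthesis genes responded more in KO cells (10 of 23, or 13 adjusted over the list alone; camera, adjusted p = 2.54e-05, and adjusted p = 0.0891 with an estimated correlation), among them HMGCR (0.79) and DHCR24 (0.76), with STARD4 the other way (-0.38). Cytotrophoblast markers responded more negatively (10 of 24, or 11 adjusted over the list alone; camera, adjusted p = 0.00141, and adjusted p = 0.0891 with an estimated correlation), among them TFAP2C (-0.88) and PEG10 (-0.74), with EGFR the other way (0.59). Cell fusion genes did so too (6 of 19; camera, adjusted p = 0.0197, and adjusted p = 0.244 with an estimated correlation), including SLC1A4 (-0.82) and ERVW-1, but not without control DMSO replicate 2 (adjusted p = 0.105), control FSK replicate 2 (0.115) or KO DMSO replicate 2 (0.0716). Lysosomal genes (camera, adjusted p = 0.855 and 0.618) and autophagy genes (0.962 and 0.127, but 0.0138 at 24 h without KO FSK replicate 1) were not called. At 24 h mitochondrially encoded mRNAs (0.127) were called without control FSK replicate 1 (0.00235), KO DMSO replicate 1 (0.0278) or KO FSK replicate 2 (0.0264), cell cycle genes (0.257) without KO FSK replicate 1 (0.0163), and steroidogenesis genes and V-ATPase subunits (0.0911 each) without KO FSK replicate 2 (0.0264 each). SQSTM1 (-1.12) and ATG9B (-1.43) responded less at 24 h.

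The test called 270 genes with a more positive and 363 with a more negative response in KO cells at 12 h, and 896 and 1258 at 24 h (edgeR). The count at 12 h, 633, was 372 to 419 without any one 12 h library except KO FSK replicate 2, and the count at 24 h, 2154, was 3428 without KO FSK replicate 2. GPC4 (4.63) and CCKBR (3.82) topped the 24 h calls from a handful of KO counts (GPC4 0 in DMSO and 6 in FSK over the group). KO FSK replicate 1 at 24 h held 26 counts over GPC4, CCKBR, ATIC and LRP2, 0.692% of the control level, against 0 to 4 in each other KO library, and whether these reads came from KO cells is not known (genes chosen after their values were seen). Without KO FSK replicate 1 they stood at 4.03 (adjusted p = 0.154) and 1.22 (adjusted p = 0.75), and leaving out any other of the 24 h libraries except KO FSK replicate 2 also ended both calls.

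Genes called with FSK in control cells were followed at the other time, in other libraries. None were picked in KO cells, so the pick could favour weaker KO responses. The 3624 genes called higher in control cells at 12 h had a median FSK response at 24 h of 0.411 in control and 0.357 in KO cells, with a median difference of -0.037, below the -0.015 to 0.012 of 10000 random gene sets (permutation p = 1e-04, the smallest they can give). For the 3365 genes called lower, the median difference at 24 h was -0.033, within the -0.036 to 0.004 of random sets (permutation p = 5e-04), and it was -0.027 (p = 0.541) without KO FSK replicate 2. Without KO FSK replicate 1 at 24 h the differences of the genes higher and lower at 12 h were -0.002 and -0.019, and that of the lower genes was -0.05 and -0.055 without control DMSO replicate 1 at 12 or 24 h. Genes called higher at 24 h had a median difference of -0.01 at 12 h, against 0.002 to 0.023 in random sets, and genes called lower had 0.016, against -0.01 to 0.015 (permutation p = 1e-04 for each, the smallest possible). The former was -0.018 and -0.003 without control DMSO replicate 1 or 2 at 12 h, -0.017 without control DMSO or FSK replicate 2 at 24 h and -0.018 without KO FSK replicate 2 at 12 h. The latter was 0.002 without control DMSO replicate 1 at 12 h and 0.008 without either KO FSK library at 12 h. For genes called lower at 24 h the sign changed with library size alone (-0.003), with no filter (-0.005) and at 2-fold or more (-0.035). Genes changed at least 2-fold differed more in the other tests as well, by -0.199 and -0.273 for those higher and lower at 12 h and -0.093 for those higher at 24 h (permutation p = 5e-04 for each). RLE scaling, no filter, 1 CPM in 2 libraries and DESeq2 gave -0.015 to -0.013 for genes higher and -0.016 to -0.002 for genes lower at 12 h, and library size alone gave -0.002 for the latter (permutation p = 0.146). For genes higher at 24 h library size alone, no filter and 1 CPM in 2 libraries gave -0.046, -0.031 and -0.017.

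Last, 24 h was set against 12 h, to see how the cells drifted in DMSO and how the FSK response developed. In DMSO the immediate-early gene EGR1 rose most in both genotypes (5.12 ± 0.45 in control and 7.08 ± 0.43 in KO cells, adjusted p = 0.000163 and 5.45e-06). The counts were 1387 higher and 1144 lower in control cells, 2531 in all, and 3043 and 2354 in KO cells, 5397 in all (edgeR). They were 922 to 1342 without any one of the control libraries, and 3262 to 3571 without any one of the KO libraries except replicate 2 at 24 h.

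Of the fixed genes, the FSK response in control cells was more positive at 24 than at 12 h for CGB5 at 1.38 ± 0.11, CGB8 at 1.37 ± 0.13, CGB3 at 1.25 ± 0.16, ERVFRD-1 at 0.95 ± 0.16, CGA at 0.71 ± 0.09, SDC1 at 0.62 ± 0.08, TFE3 at 0.49 ± 0.09 and ERVW-1 at 0.37 ± 0.11 (adjusted p = 0.0377), and more negative for TFEB at -0.37 ± 0.10 (0.0162). In KO cells it was more positive for CGA (1.03), CGB8 (1.11, adjusted p = 0.0245) and SDC1 (0.34) and more negative for ERVW-1 (-0.35, adjusted p = 0.0457). GPRC5A (2.80), the mTOR inhibitor DDIT4 (2.65) and TNFSF10, the death ligand TRAIL (2.39), had the largest gains in control cells. The responses of 975 genes were more positive and 590 more negative at 24 h in control cells, and 886 and 914 in KO cells (edgeR). With library size alone the share of the former was 37.3% against 62.3% in control and 36.1% against 49.2% in KO cells. Between genotypes this change differed for 227 genes, 68 more positive and 159 more negative in KO cells, among them CCND1, cyclin D1 (1.59), and ERVW-1 (-0.72 ± 0.15, adjusted p = 0.0232). The calls of ERVW-1 in these 3 contrasts, of TFEB and of CGB8 in KO cells were each lost without any one of 4 or more libraries. Leaving out single libraries moved the 1565 genes of control cells to 899 to 1111, the 1800 of KO cells to 1120 to 3321, and the 227 to 113 to 776.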

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

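The differences given here were tested as planned, and of the tests on ERVFRD-1 and the CGB genes below only the one on GCM1 was chosen after the result was seen. Each result was picked out because the FSK response differed between KO and control cells, or between 12 and 24 h, by a test of the difference itself. No group held enough samples to look for a single sample far from the others, and no measured column lay outside the comparisons.

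At 12 h the response differed for 633 genes, a count that was 408 or 412 without control DMSO replicate 1 or 2, 379 or 396 without control FSK replicate 1 or 2, 419 or 372 without KO DMSO replicate 1 or 2, and 380 without KO FSK replicate 1. The differences on the log2 scale were positive for CGA (1.10), CGB3 (1.80), CGB5 (2.31), CGB8 (2.06), ATL3 (1.93) and PADI1 (1.84). They were negative for TFEB (-0.80), WNT3A (-4.64), HTRA4 (-2.58), PGC (-2.34), PDLIM3 (-2.34) and RGS12 (-2.29). The WNT3A call ended without KO DMSO replicate 1 (-2.96, adjusted p = 0.629), and the ATL3 call without KO DMSO replicate 2 (1.74, adjusted p = 0.0888) or KO FSK replicate 2 (1.73, adjusted p = 0.0882). Of the lists, the integrated stress response had a median difference of -0.44 and interferon-stimulated genes of -0.27. With an estimated correlation neither was called (adjusted p = 0.113 and 0.615). The second was not called with library size alone (0.0565), with 1 CPM in 2 libraries (0.0507), or without control DMSO replicate 1 (adjusted p = 0.066), control FSK replicate 1 (0.145), KO DMSO replicate 1 (0.367) or KO FSK replicate 1 (0.158).

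At 24 h it differed for 2154 genes, or 3428 without KO FSK replicate 2. Positive differences were those of CGA (1.41), CGB3 (1.29), CGB5 (1.47), CGB8 (1.81), PKP2 (2.63), PARP14 (2.62), SORL1 (2.38), GPC4 (4.63) and CCKBR (3.82). Negative ones were those of TFEB (-0.65), TFE3 (-0.43), ERVW-1 (-0.60), HTRA4 (-3.78), CCDC187 (-3.53), GREB1 (-3.30), SIGLEC6 (-3.12) and SP6 (-2.73). CGB3 lost its call without KO DMSO replicate 1 (1.01, adjusted p = 0.075) or KO FSK replicate 2 (1.20, adjusted p = 0.0577). GPC4 and CCKBR rested on few counts in KO cells. Both lost their calls without any one of the 24 h libraries except KO FSK replicate 2 (4.03 to 4.67 and 1.22 to 6.04). Median differences of the lists were -0.30 for cell fusion genes, -0.23 for cytotrophoblast markers, 0.26 for cholesterol biosynthesis, -0.36 for the integrated stress response and -0.42 for interferon-stimulated genes. With an estimated correlation none of these lists was called (adjusted p = 0.244, 0.0891, 0.0891, 0.097 and 0.244, in that order). The cell fusion list was not called without control DMSO replicate 2 (adjusted p = 0.105), control FSK replicate 2 (0.115) or KO DMSO replicate 2 (0.0716).

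Between 12 and 24 h the FSK response differed for 1565 genes in control and 1800 in KO cells. In control cells the count was 921 or 979 without DMSO replicate 1 at 12 or 24 h, 899 or 980 without FSK replicate 1 or 2 at 12 h, and 925 without FSK replicate 2 at 24 h. In KO cells it was 1177 or 1120 without DMSO replicate 1 or 2 at 12 h, 1161 without FSK replicate 1 at 12 h and 3321 without FSK replicate 2 at 24 h. The change itself differed between genotypes for 227 genes, among them ERVW-1 (-0.72). That count was 657 or 776 without KO FSK replicate 1 or 2 at 24 h, and smaller without any of the 4 control DMSO libraries (115, 128, 141 and 124), control FSK replicate 1 or 2 at 12 h (113 and 131) and replicate 2 at 24 h (122), KO DMSO replicate 1 or 2 at 12 h (137 and 115), and KO FSK replicate 1 at 12 h (137).

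ERVFRD-1 and the CGB genes stood far lower in KO than in control cells. From this low level FSK raised the CGB sum in KO cells (7.31 to 142 CPM at 24 h), arguing against full CGB loss. Wide loss around a locus was excluded (lowest median of 20 genes -0.27). At 12 h single neighbours fell to -3.55 (CGB, DMSO) and -2.05 (ERVFRD-1, FSK). Reads moved between paralogs were excluded, as the log2 ratio of the summed CGB genes and LHB was -5.16 and -5.01 in DMSO and -3.28 and -3.70 in FSK at 12 and 24 h. A lower level of GCM1 mRNA was excluded too, since the lowest of its 4 fold changes was 0.24. An effect of the TFEB loss, a short or partial loss and other differences between the lines stay open with a single line per genotype.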

How the results depend on the processing

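The alternatives in this part were planned, and no test in it was chosen after the result was seen. Total counts of called genes for FSK against DMSO and for KO against control stayed within 1.5 times the reported ones under each alternative run, but counts by direction did not. With library size alone FSK in control cells at 24 h called 2554 genes higher (against 4234) and 6318 lower (against 3990), and in KO cells 2394 higher at 12 h (against 3712) and 2677 at 24 h (against 4328), and the change of the response with time in control cells called 1101 lower (against 590). With no filter on low counts that change called 1395 higher in KO cells (against 886), and its difference between genotypes 157 higher (against 68). With DESeq2 the change in KO cells called 587 lower (against 914). Single libraries left out gave 5358 to 5480 and 6692 to 6890 genes for FSK in control cells at 12 and 24 h, and 5414 to 5828 and 7423 to 8764 in KO cells. For KO against control they gave 4514 to 4778 and 5201 to 5698 in DMSO, and 5022 to 5399 and 6322 to 8067 in FSK. A lone library of a group was then assumed to vary like those of the other groups.

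With RLE scaling TFE3 in KO against control DMSO cells at 24 h was -0.01, as it was with no filter on low counts and with DESeq2, against 0.02. MITF with FSK in control cells was, with library size alone, -0.07 at 12 h and -0.11 at 24 h, ERVW-1 at 12 h -0.03 and TFEB at 24 h 0. None of these values was called under either setting. The lists called for the difference of the FSK response at 12 h went from 2 to 1 with library size alone and with a filter of 1 CPM in 2 libraries, where MITF with FSK in control cells at 12 h was 0. With no filter the difference between times of the KO change in the FSK response called 353 genes, against 227. Genes lower with FSK at 24 h had a median difference at 12 h of -0.003 with library size alone, -0.005 with no filter and -0.035 when picked at 2-fold or more, against 0.016, and genes lower at 12 h had -0.002 with library size alone, against -0.033. Picking at 2-fold or more moved the others further from 0, to -0.199 and -0.273 at 24 h and -0.093 at 12 h. The cause was not tested.

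Fitting only the groups compared, which leaves fewer samples for the estimate of spread, called 1360 and 1322 genes for the difference of the FSK response at 12 and 24 h, 3996 for time in control DMSO cells, and 3235 and 834 for the change of the FSK response with time in control and KO cells. Each part by direction of these 5 counts moved by over 1.5 times too. This alternative was not run for the carry-over test, and it equals the reported fit where all 8 groups are compared. With an estimated correlation camera called 4 and 5 lists for FSK in control cells at 12 and 24 h, 3 and 5 in KO cells, 2, 3, 0 and 0 for KO against control in DMSO at 12 and 24 h and FSK at 12 and 24 h, and 0 and 0 for the difference of the response, against 9, 10, 10, 8, 9, 9, 9, 9, 2 and 5. Fry, which does not compare a list with other genes, called 17 for FSK in control cells at 12 h and 17 in KO cells at 24 h, 15, 16, 14 and 15 for KO against control, and 5 and 11 for the difference. With the 1 CPM filter the pregnancy-specific glycoproteins gave no value.

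The labels do not say that a replicate number marks a shared batch or day, so the samples were taken to share only a number. Of 28 pairs of groups, the correlation of the difference between replicates was over 0.1 in 11 and under -0.1 in 0 (-0.091 to 0.377, median 0.074). The 6 pairs within the KO groups ranged from 0.118 to 0.377, so a batch shared among KO libraries was not excluded. A fit with the replicate number as a block called 769 and 2465 genes for the difference of the FSK response at 12 and 24 h, against 633 and 2154. Of 45 counts of genes 44 stayed within 1.5 times (the other, the difference between genotypes of the change with time, had 106 higher, against 68). With the block the MiT/TFE list in KO against control DMSO cells at 12 h (adjusted p = 0.059), the cell fusion list in FSK at 24 h (0.057) and interferon-stimulated genes for the difference at 12 h (0.0503, leaving 1 list) were not called, and autophagy with FSK in control cells at 24 h was (0.0483). Calls gained among the fixed genes were TFEB with FSK in control cells at 24 h (0.0413), ERVW-1 with FSK in KO cells (0.0335 and 0.0257), GCM1 in DMSO at 12 h (0.00901) and its difference at 24 h (0.0352), and CGA in FSK at 12 h (0.0258).

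Leaving out single libraries gave 372 to 475 and 1498 to 3428 genes for the difference of the FSK response at 12 and 24 h, and 922 to 1342 and 3262 to 4302 for time in control and KO DMSO cells. It gave 899 to 1111 and 1120 to 3321 (without KO FSK replicate 2 at 24 h) for the change of the response with time in control and KO cells, and 113 to 776 for its difference. Lists called for the difference of the response were 1 to 2 at 12 h, with 1 without control DMSO replicate 1, control FSK replicate 1, KO DMSO replicate 1 or KO FSK replicate 1. At 24 h they were 4 to 8, with 8 without KO FSK replicate 2. Genes lower with FSK at 12 h had a median difference at 24 h of -0.055 to -0.019, and it was -0.027 without KO FSK replicate 2 at 24 h, where the permutation p was 0.541, against 5e-04 to 0.0025 without each other library. These values crossed 0: MITF with FSK in control cells at 12 h (-0.09 to 0.11), in KO cells at 12 h (-0.75 to 0.19) and at 24 h (-0.05 to 0.37), its difference at 12 h (-0.77 to 0.18) and at 24 h (-0.12 to 0.32), TFE3 in KO against control DMSO cells at 24 h (-0.02 to 0.06), its difference at 12 h (-0.12 to 0.03), ERVFRD-1's difference at 24 h (-0.08 to 0.56) and ERVW-1 in KO against control FSK cells at 24 h (-0.22 to 0.06). ERVW-1 was called at -0.22, without KO FSK replicate 2 (adjusted p = 0.00356, against 0.227 to 0.981 without the other libraries of the 2 groups), and the others were not called. The cause was not tested.

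Of the values of named genes, leaving out libraries kept direction and call in 5355, ended the call in 612, added it in 6 and turned the sign in 11. With DESeq2 49 calls ended. Library size alone ended 58 and added 2, and with RLE scaling 10 ended and 2 were added. Depth limited genes with 0 counts over a group, such as FN1 in KO DMSO cells at 12 h, whose fold change could be given only at the floor.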

Other observations

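The gene families in this part and the tests on DNA replication genes, on small RNAs without poly(A) at 1 CPM or more and on runs of lowered genes were chosen after the result was seen. Metallothioneins, small metal-binding proteins, went both ways in KO cells. Of the 7 genes tested, MT1G and MT1H, at 1.1 and 1.4 CPM in control cells, were nearly absent from KO cells (1 and 6 counts over the 8 KO libraries). Of the 5 members with an average log2 CPM above 0, in KO against control DMSO cells 3 rose at 12 h and 5 at 24 h (medians 0.47 and 1.87), and in FSK 3 and 5 (1.10 and 1.54). Between 12 and 24 h in DMSO these 5 members rose in KO cells (median 1.11), while 0 passed in control cells (0.23), a difference between genotypes that was not tested.

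Clustered protocadherins, adhesion molecules that are read from neighbouring promoters, were counted gene by gene, with no test against other genes. Of 10 beta genes at that level 8, 7, 7 and 5 rose in DMSO at 12 and 24 h and FSK at 12 and 24 h (medians 0.85, 0.78, 0.96 and 0.69), and of 9 gamma genes 5, 6, 7 and 4 (0.62, 0.75, 0.86 and 0.70), with 0 lower. Of the 5 beta and 12 gamma genes below that level, 1, 1, 3 and 2 and 3, 1, 2 and 1 rose and 0 fell. The gamma genes share their last exons, so reads are uncertain between them.

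In KO libraries 148 genes with a signal in control cells, 108 of them protein coding, had at most 3 counts per library on average, against 8 and 2 the other way round. Loss of segments with several genes was excluded as the cause for the set as a whole, since its 508 tested neighbours had a median of -0.08 (bootstrap interval -0.11 to -0.04), but not for 13 of the 14 genes, of 132, whose 4 neighbours had medians of -1 or lower (at most 9 in 1000 random sets of like expression), as at BDKRB2 (-2.81), TCL6 and TCL1B (-2.3 each), CYP2J2 (-2.53) and PRKAA2 (-1.64), where loss and silencing of a region were not separated, while CGB2 (-4.41) lay among 4 CGB or LHB genes, around which flanking genes had medians of -0.27 or higher. With 50-gene window medians removed, 4.52% fewer genes lay beyond 2-fold in DMSO at 12 h (1572 to 1501) and 3.26% at 24 h. Copy number stays open for smaller changes and shorter segments. The 148 against 8 argue against a low starting level (median 0.638 CPM in control cells) for the set. It fails for ATIC (55.8 CPM), CCKBR (44.2), LRP2 (37.9) and GPC4 (21.4). What also stays open is that KO and control cells may come from different clones, which the design confounds with the knockout. Regional differences stay open, as window medians ran from -0.68 to 0.7. They spread more than in any of 100 shuffled orders (SD 0.132 against 0.0567 at most at 12 h, 0.124 against 0.061 at 24 h).

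Replication-dependent histones were called lower in KO cells at 12 h (medians over 9 members of -0.84 in DMSO and -1.42 in FSK), but not with an estimated correlation (adjusted p = 0.156 and 0.088), and were not called at 24 h (-0.41 and -0.84, adjusted p = 0.221 and 0.101). Small RNAs did not show less carry-over of RNA without poly(A), but histone mRNAs may differ. The 46 had a median of -0.07 in FSK at 12 h (bootstrap interval -0.16 to 0.08) at only 0.565 CPM. The 10 at 1 CPM or more had 0 (-0.19 to 0.16). Fewer cells in S phase could not be decided, as 14 DNA replication genes, 3 of them called lower and 1 higher, had a median of -0.04 (-0.13 to 0.03), an interval above the -0.3 set for this cause but reaching below the -0.1 set against it. No biological explanation beyond this was tested.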
